A study of Arabidopsis thaliana with 6 samples.

How the data were processed

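Expression was measured in 6 samples of whole Arabidopsis Col-0 seedlings, 3 fumigated with ozone and 3 with scrubbed air, each on 1 Affymetrix ATH1 array. The deposited values are MAS5 signal intensities on a linear scale, 1 per probe set and array, per the submitters' processing notes, which name MAS5 without a version. MAS5 combines the probe pairs of a probe set into 1 signal and scales each array; in the deposited values the mean after trimming 2% at either end was 100 on every array, which is read from the values. Detection calls and the scaling target were not used and are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

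All values were taken to log2 without a pseudocount, after 95 zeros were set to the smallest positive signal of their array. No further normalization was applied. The 64 control probe sets were left out, and probe sets with a mean log2 signal below the 40th percentile (a signal of 31.2) were left out before testing, which kept 13648. MAS5 signals this dim hold much noise, so a large fold against a dim group is imprecise. Ozone was compared with control by limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend on level, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Every adjusted p for a gene comes from this fit unless another setting is named. Log2 fold changes are ozone minus control, and means ± SD are of the linear signal. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

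Probe sets were named through the platform's annotation table. It lists 13513 probe sets with 1 gene and 503 with several, while 8730 are unnamed here, and none was named from a probe set with several genes. Through gene identifiers 13436 probe sets matched a locus of the RefSeq table for TAIR10.1, which was used only for names. Few genes with a symbol are covered: 1530 of the 10492 protein-coding genes with a symbol of their own have a probe set that names them alone. Where several probe sets measured a locus, the one with the highest mean signal stood for it, which gave 7250 loci.

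Before the data were examined, 31 gene lists with 621 members, the tests, the alternatives and a rule for named genes were fixed. The rule takes the 12 genes per direction with the largest log2 fold change among those past the threshold, with 1 gene, a brighter group at or above the median signal of 46.4 and no overlap of the groups. It adds the 5 smallest p per direction, the 3 smallest p of each list with the member of smallest p going the other way, and all tested reference genes and markers of other cell types. Of the 621 members, 86 have a probe set of their own and 74 were tested. The lists of cysteine-rich receptor-like kinases, senescence, cell cycle and phloem genes had 0 tested members, and 22 lists had 1 to 3, so a list's count here describes few of its genes. The 5 lists with at least 4 tested members were tested with camera (preset correlation 0.01), beside an estimated correlation and fry.

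The titles number the replicates 1 to 3 in both groups without saying what a number stands for. They also hold a serial number that alternates between ozone and control in the order of the replicate numbers. Its meaning is not given either. Deviations from the group means, correlated across probe sets, had r = 0.747, 0.374 and 0.439 for replicates 1, 2 and 3. All 3 were above 0.1, the bound for reading the number as pairing the arrays. Deviations within a group cancel out, so the 3 values are not independent of each other. The main fit has no block. The fit with the number as a block is given where it changes a call or moves a count by over 1.5 times. Control replicate 2 correlated about as well with ozone replicate 3 (0.413), and control replicate 3 with ozone replicate 2 (0.368), so the shared deviation mainly parts replicate 1 from replicates 2 and 3.

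Alternatives were quantile normalization, median centring, 16 or 64 added to the signal, no filter or a filter at the 60th percentile, eBayes without a trend or with robust estimation, the block, leaving out probe sets shared between transcripts, and leaving out each array in turn. Leaving out both arrays numbered 1, testing families by gene symbol, counting calls within families under each setting and ranking genes with 16 added were chosen after the data were seen. The code was tested on simulated data with 13648 probe sets, the real means, the spreads moderated by eBayes and 200 changed genes per run in 5 runs. Probe sets were drawn independently, so the simulation lacks the deviation that the replicate 1 arrays share. The fit recovered 1.49% of genes changed 1.5-fold, 42.4% of those changed 2-fold and 97.6% of those changed 4-fold, all with the right sign. Of 511 calls 42 were false, a larger share than the threshold for the adjusted p. In the real comparison 3816 probe sets passed, far more than the 200 changed per simulated run. The adjustment is less strict when more probe sets change, so these shares do not give the recovery in the real comparison.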

Results

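Transcript levels were measured in whole seedlings of the Arabidopsis accession Col-0 that had been fumigated for 6 h with 500 ppb ozone, a gas that forms reactive oxygen species when it enters leaves, or with scrubbed air as the control. Seedlings were grown on 0.8% agar at 20 °C under 16 h light and 8 h dark, were fumigated in their growth plates at developmental stage 1.04, and were extracted directly afterwards. Each group had 3 replicates, and each replicate was hybridized to 1 Affymetrix ATH1 array with 22810 probe sets. The median signal of an array lay between 41.7 and 49.5, and the number of arrays limits the precision of every value below.

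Spearman correlations between arrays, across probe sets, were 0.952 to 0.983 within the control group, 0.956 to 0.975 within the ozone group and 0.879 to 0.930 between the groups. The first principal component of the tested probe sets held 69.7% of the variance and placed all 3 ozone arrays apart from all 3 control arrays. The second held 21.45% and placed replicate 1 of both groups apart from replicates 2 and 3. Ozone replicate 3 lay closest to the controls on the first component, at 32.9 against 57.8 and 59.3 for ozone replicates 1 and 2.

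**Figure D1:**
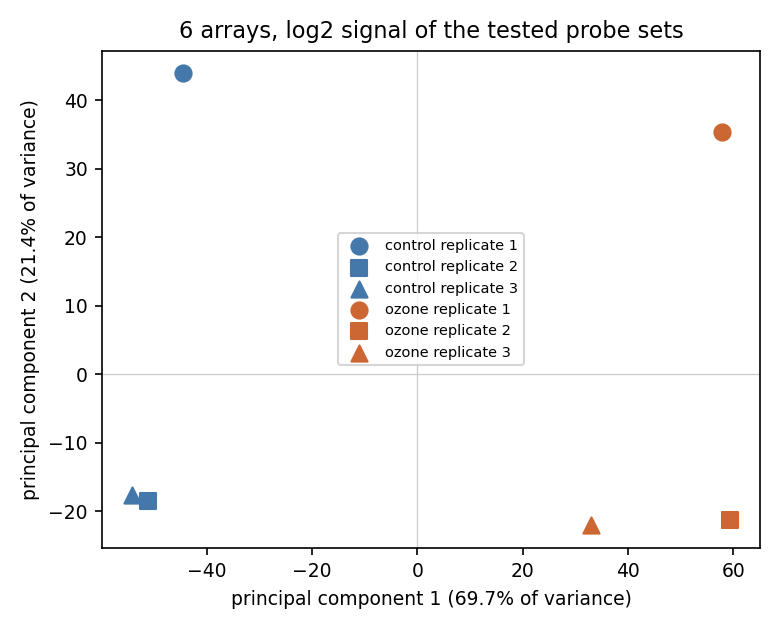
Scores of the 6 arrays on the first and second principal components (no unit) of the log2 signals of 13648 probe sets, with colour for the group and marker shape for the replicate number. The control arrays lie between -54.2 and -44.6 on the first axis and the ozone arrays between 32.9 and 59.3, while replicate 1 of either group lies at 35.4 or above on the second axis and the other 4 arrays lie at -17.6 or below.

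The comparison of ozone with scrubbed air asked which transcripts differ after ozone exposure. Genes are ranked here among probe sets that name 1 gene, whose groups do not overlap and whose brighter group is at or above the median signal of 46.4. Of the 13648 tested probe sets 7313 have a locus, as do 1902 of the 3816 changed ones, and the rest could not be ranked. The 12 with the steepest rise in this ranking had control means of 2.90 to 47.0 and ozone means of 240 to 1297. AT1G57630, which encodes a protein with a TIR domain as found in plant immune receptors, went from a signal of 2.90 ± 0.781 to 535 ± 29.5 (SD, n = 3 each), a log2 fold change of 7.56 (SE 0.229, limma adjusted p = 9.31e-06). AT2G32190 and AT1G56060, which encode small proteins with a cysteine-rich transmembrane module, rose by log2 fold changes of 6.13 and 5.15. JRG21 and AT2G38240, 2-oxoglutarate-dependent oxygenases that hydroxylate jasmonate, rose by 5.05 and 4.84. In the other direction EXPA8, an expansin that loosens cell walls, fell from 249 ± 32.9 to 38.8 ± 35.1 (SD, n = 3 each), a log2 fold change of -3.08 (SE 0.576, limma adjusted p = 0.00666).

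Other genes among the 12 with the highest rise in this ranking were AT1G10585, a basic helix-loop-helix transcription factor (log2 fold change 7.07), AT3G60420 of the phosphoglycerate mutase family (5.38), the lipid flippase gene AT3G25610 (5.37) and AT1G26380, a berberine bridge enzyme-like oxidoreductase (5.31). They also included the glycolipid transfer protein gene AT4G39670 (5.23), AT1G19020 (4.79) and the lipase gene AT5G24210 (4.71). AT2G18690 (log2 fold change 4.68) and AT2G23680 (4.31, or 2.76 with 16 added to every signal) completed the 5 rising genes with the smallest p. A fold against low control signals depends on how low signals are treated. For 10 of the 12 the control mean was below the filter level of 31.2, so their folds and order are uncertain. With 16 added to every signal the log2 fold changes of the 12 genes were 3.103 to 4.87 and 9 of them stayed among the 12 with the steepest rise. AT5G24210, AT3G25610 and JRG21 left and AT2G18690, AT1G05340 and AT3G16530 took their places.

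In the same ranking the 12 with the steepest fall had log2 fold changes of -3.08 to -2.11, or -2.45 to -1.46 with 16 added to every signal, where 7 stayed among the 12. The ozone mean of 6 was below the filter level, and 5 of these 6 left: AT1G67750, AT4G26010, AT5G12110, AT5G50740 and AT1G22630. Beside EXPA8 they included the pectate lyase gene AT1G67750 (log2 fold change -2.44), the peroxidase AT4G26010 (-2.18) and the GDSL lipase AT1G29660 (-2.40). DRT100, a leucine-rich repeat protein gene, fell by 2.35 on the log2 scale, and the acyltransferase gene AT4G15390 fell by 2.31. The others were AT2G03310 (-3.07), the DNA glycosylase-family gene AT5G44680 (-2.78), AT5G11420 (-2.40), AT5G12110 (-2.25), the heavy-metal-associated domain gene AT5G50740 (-2.12) and AT1G22630 (-2.11). Genes with smaller falls but among the 5 smallest p were AT2G34620 of the mitochondrial transcription termination factor family (-2.03), AT4G12980 (-1.82), AT1G75460 with a LON protease domain (-1.52) and the pentatricopeptide repeat gene AT5G42310 (-1.42).

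**Figure D2:**
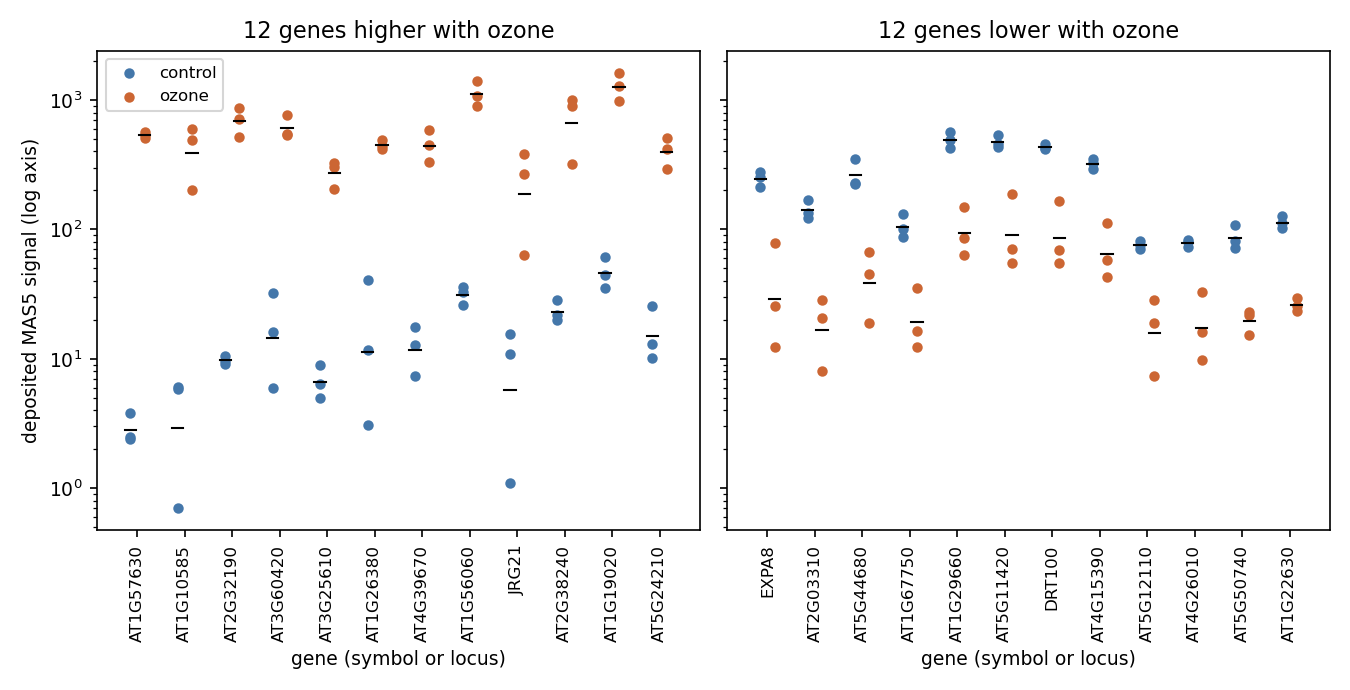
MAS5 signal (log axis) of the 12 genes with the steepest rise (left) and the 12 with the steepest fall (right) among probe sets that name 1 gene; each point is 1 array, blue for control and orange for ozone, and the black bar is the geometric mean of 3 arrays. The genes were chosen with no overlap of the groups; the control means on the left run from 2.90 to 47.0, and the ozone means on the right from 18.3 to 104.

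Across the array, 3816 of 13648 tested probe sets (28.0%) changed with ozone at a limma adjusted p under 0.05, 1777 of them higher and 2039 lower. The larger direction depended on the setting: 46.6% of the calls were higher, against 53.3% of 3430 calls with each array centred on its median and 50.9% of 3726 without the filter on dim probe sets. The median log2 fold change of all tested probe sets was -0.154. Changes of at least 2-fold were 1977, of which 1201 were higher and 776 lower. At the level of single loci, 1896 of 7250 changed, 854 higher and 1042 lower. The groups did not overlap at 3227 of the 7250 loci, where chance alone gives 10% per locus. All loci share the same 6 arrays and do not vary independently, so this excess is no test. With the replicate number as a block 6699 probe sets changed, 2602 higher and 4097 lower, and all 3816 were among them. Without ozone replicate 2, control replicate 2 or control replicate 3 the number was 2246, 2408 and 2273. Adding 64 to every signal left 918 changes of at least 2-fold, 722 higher and 196 lower.

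Of 5 tested antioxidant enzyme genes, 2 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone. The monodehydroascorbate reductase gene ATMDAR2, whose product regenerates ascorbate, rose 3.67-fold from 256 ± 18.3 to 947 ± 163, and the cytosolic glutathione reductase gene GR1 rose 2.71-fold (log2 fold change 1.44, SE 0.244, adjusted p = 0.00448). The thylakoid ascorbate peroxidase gene TAPX fell (log2 fold change -0.65, adjusted p = 0.0228). Its adjusted p was 0.0843, 0.0517 and 0.0785 without ozone replicate 2, control replicate 1 or control replicate 3, and 0.0602 with each array centred on its median. The plastid glutathione reductase gene GR had a log2 fold change of -0.62 (adjusted p = 0.124, and 0.00365 with the block). Among 7 glutathione S-transferase genes, 1 rose, 3 fell and 3 did not pass; adjusted over the list alone, 2 rose and 4 fell, and the block gave the same 2 and 4. GSTU25 rose 2.35-fold (adjusted p = 0.00966), while GSTU26 fell by 1.09 on the log2 scale (adjusted p = 0.00169). These enzymes couple glutathione to reactive compounds.

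Of 3 tested genes of the mitochondrial dysfunction response 2 rose. NDB2, an external NAD(P)H dehydrogenase of mitochondria, rose 8.76-fold from 73.5 ± 6.67 to 648 ± 103 (adjusted p = 4.25e-05), and AT2G21640, known as UPOX, rose 3.01-fold. The remaining tested member of that list, AT5G09570, had a log2 fold change of 0.11 (adjusted p = 0.748). The zinc finger gene STZ (also ZAT10), the single tested member of the oxidative stress signalling list, rose 14.8-fold, from 44.7 ± 31.4 to 667 ± 435 (adjusted p = 0.00271). With 16 added to every signal the log2 fold change was 3.395 for STZ, against 3.89, and 1.25 for AT2G21640, against 1.59. Both tested members of the heat shock list rose, the small heat shock protein gene AT5G51440 by a log2 fold change of 3.19 and the immunophilin gene AT5G48570 by 1.42, or 2.16 and 0.966 with 16 added to every signal, since their control means were 12.4 and 21.5. BZIP60, a transcription factor of the unfolded protein response, rose by 1.98 (adjusted p = 0.000132).

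Defence and hormone genes that could be tested were few. Of 3 WRKY genes 1 passed: WRKY6 rose 7.56-fold (log2 fold change 2.92, or 2.40 with 16 added to every signal; adjusted p = 0.000369), while WRKY22 and WRKY47 had log2 fold changes of 0.59 and 0.04 and did not pass. The receptor-like cytoplasmic kinase gene BIK1 rose 3.06-fold, the immune regulator gene SAG101 rose 2.60-fold (log2 fold change 1.38, or 0.982 with 16 added) and OPCL1, which activates jasmonate precursors, rose by a log2 fold change of 2.11. GH3.3, which conjugates auxin to amino acids, rose 6.17-fold (log2 fold change 2.63, or 2.08 with 16 added), whereas WES1 (GH3.5) had a log2 fold change of -0.24 (adjusted p = 0.442). EIN3, the only tested ethylene gene of the lists, had 0.28 (adjusted p = 0.447). Of 4 abscisic acid and cold response genes, the dehydrin LTI30 rose 2.35-fold, COR15B fell by 1.198 on the log2 scale and 2 did not pass; adjusted over the list alone, and with the block, 2 fell.

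AT2G04400, which encodes indole-3-glycerol phosphate synthase of the tryptophan pathway, rose 4.44-fold from 200 ± 2.07 to 892 ± 97.6 (adjusted p = 0.000104). The cinnamoyl-CoA reductase gene CCR2 rose 7.09-fold from a dim 15.4 (log2 fold change 2.83, or 1.97 with 16 added to every signal), and HCT, an acyltransferase of lignin synthesis, rose 1.60-fold (adjusted p = 0.0102, and 0.0545 without control replicate 2). The shikimate pathway gene AT5G66120 had a log2 fold change of 0.57 (adjusted p = 0.0595, and 0.00557 with the block). The flavonoid genes DFR, UGT78D2 and UF3GT had log2 fold changes of 0.04, -0.22 and 0.24, and 0 of these 3 passed. In the aliphatic glucosinolate list UGT74B1 rose (0.71), AT2G31790 fell (-0.77) and BCAT4 did not pass (-0.51); adjusted over the list alone, and with the block, 2 fell. The adjusted p was 0.0601 and 0.0564 for UGT74B1 without ozone replicate 2 or control replicate 3, and 0.0587, 0.0561 and 0.0718 for AT2G31790 without ozone replicate 2, control replicate 2 or control replicate 3. The 3 sulfate assimilation genes APS3, APS4 and SIR had log2 fold changes of 0.41, 0.17 and 0.56 and 0 passed, while 2 rose with the block. Of 3 proteasome subunit genes, AT5G23540 rose (0.71); its adjusted p was 0.0629, 0.0720 and 0.0781 without ozone replicate 2, control replicate 2 or control replicate 3.

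Of 3 Calvin cycle genes 2 fell: PRK, which makes the substrate of Rubisco, fell from 2032 ± 259 to 1037 ± 156 (log2 fold change -0.97, SE 0.182, adjusted p = 0.00671), and SBPASE had -0.87 (adjusted p = 0.0493). The call of SBPASE was lost when any array other than ozone replicate 1 was left out (adjusted p 0.0821 to 0.163), with each array centred on its median (0.111), without the filter on dim probe sets (0.0842) and without the variance trend (0.0537). All 7 tested light harvesting and photosystem genes had negative log2 fold changes, from -0.84 to -0.20, but the size of most depended on the scaling. With quantile normalization PSAE-1 turned to 0.07, and LHCB4.1 went from -0.27 to -0.068, PSBW from -0.37 to -0.143, PSBY from -0.55 to -0.323 and PSAN from -0.46 to -0.286. The third Calvin cycle gene, RCA, did not pass and went from -0.39 to -0.148. Of the 7, LHCB4.2 fell (adjusted p = 0.0312); adjusted over the list alone, 0 fell. LHCB4.2 was not past the threshold when any array other than ozone replicate 1 or control replicate 2 was left out (adjusted p 0.0550 to 0.114), after median centring (0.0799) or without the filter (0.0591). With the block, 6 of the 7 fell, and all 3 Calvin cycle genes did. Of the 6, PSAE-1 and LHCB4.1 passed narrowly (adjusted p = 0.0468 and 0.0441 with the block). The block was not run with quantile normalization, under which PSAE-1 changed sign. The replicate 1 arrays stood apart on these genes: PSAN, for example, had a signal of 2655 in control replicate 1 against 1239 and 1588 in the other controls. The clock gene GI had a log2 fold change of -0.72 (adjusted p = 0.0780, and 0.00136 with the block).

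Cell wall genes split. Among 7 tested expansin and xyloglucan endotransglucosylase genes 3 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone and 4 and 2 with the block. EXPA15 fell from 401 ± 95.02 to 124 ± 46.0 (log2 fold change -1.72, SE 0.287, adjusted p = 0.00417) beside EXPA8. XTH18 rose by 1.85 (adjusted p = 0.0300), with adjusted p of 0.0641, 0.0941 and 0.0885 without ozone replicate 2, control replicate 2 or control replicate 3, and it did not pass without the filter on dim probe sets.

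**Figure D3:**
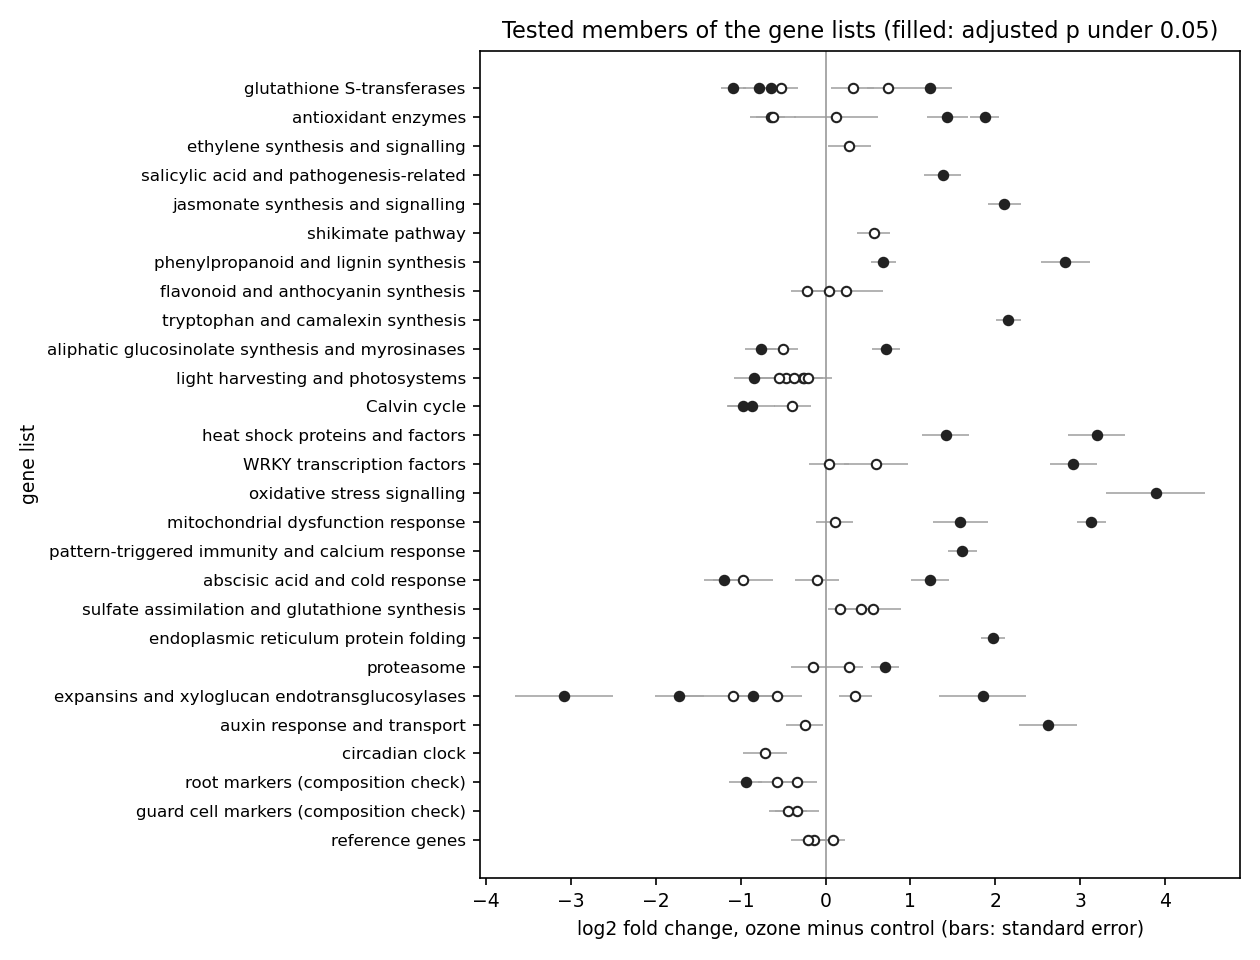
Log2 fold change (ozone minus control) of each of the 74 tested members of the gene lists, 1 row per list, with standard errors as bars; filled points have an adjusted p under 0.05. Of the members, 21 rose, 13 fell and 40 did not pass, with the largest rise for STZ (3.89) and the largest fall for EXPA8 (-3.08).

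Markers of other cell types and reference genes were read beside these groups. Of 3 tested root markers, EXPA7 fell by 0.94 on the log2 scale (adjusted p = 0.0101, and 0.0506 without control replicate 3), and EXPA18 and PYK10 had -0.57 and -0.33 and did not pass. With the block 2 fell. The ozone mean of EXPA7 was a dim 24, and its log2 fold change was -0.63 with 16 added to every signal. The guard cell genes FMA and AT1G22690 had -0.34 and -0.44, and 0 passed (1 fell with the block). The reference genes PEX4, AT4G34270 and AT2G28390 had log2 fold changes of 0.09, -0.13 and -0.21, and 0 of 3 passed with or without the block. Adjusted over the list alone, the lists without such a count above kept their counts of calls, except that 1 shikimate gene rose and 1 clock gene fell. Tests of whole lists were possible for 5 lists with at least 4 tested members, and 0 were shifted against other genes by camera, with 0 at an unadjusted p under 0.05 (adjusted p 0.437 to 0.806; 0.782 to 0.878 with an estimated correlation). Fry tests the members of a list against no change and makes no comparison with other genes. By fry the antioxidant list was higher (adjusted p = 0.0172) and the expansin and xyloglucan endotransglucosylase list lower (0.0323). With the block these adjusted p-values were 0.0637 and 0.197. Members of both lists went both ways, with median log2 fold changes of 0.125 and -0.854. Neither call therefore means that the whole list moved. Without the filter on dim probe sets camera with the preset correlation called 3 lists, those of heat shock, WRKY and immunity and calcium genes. Each has 4 members with a probe set of their own, and an estimated correlation was not run in that setting.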

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

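The array's control probe sets were left out of the comparison, and 5 of the 19 that measure Arabidopsis transcripts or ribosomal RNA were higher on every ozone array than on every control array, while 0 were lower on every ozone array. They measure ubiquitin, with log2 differences of 0.603 for the 5' probe set and 0.782 for the middle one, and GAPDH, with 0.199 and 0.315 for 2 probe sets at the 3' end and 0.246 for a 5' one. The other 3 ubiquitin probe sets had 0.157, 0.000 and 0.355 and the other 2 for GAPDH 0.481 and 0.135, with overlap of the groups. What drew attention is a difference between the groups in data outside the main measurement. Groups without overlap were common on these arrays: in either direction they were found at 3227 of the 7250 tested loci. That is a larger share than 5 of 19, so the 5 do not stand out by it. All 5 measure ubiquitin or GAPDH, so they are not independent of each other. The smallest exact permutation p (two-sided) that 3 against 3 arrays allow is 0.1, so that test cannot reach 0.05 for any of them, and no model-based test was run on the control probe sets.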

How the results depend on the processing

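The setting that leaves out both arrays numbered 1 was chosen after the data were seen; the others were planned. Among the 3816 changed probe sets, 0 turned direction under any setting that still tested them. The count stayed within 1.5 times under all settings but these: the replicate block gave 6699 (4097 lower), and leaving out 1 array gave 2246 to 3690 changed and 987 to 1933 lower, with fewer arrays in the fit. Without both arrays numbered 1 it was 4839. Changes of at least 2-fold numbered 918 with 64 added to the signal, 722 higher and 196 lower, and 502 lower with 16 added, since a pseudocount shrinks folds by construction. Camera called 3 lists without the filter, where more lists have 4 members, and fry called 2. All other settings gave 0, the block included. The block ended no call among named genes. Apart from the calls given beside single results and lists, it changed no other call of a list. Of 87 genes named or in called families, all past the threshold, 71 to 84 kept the call when 1 array was left out, and 80 to 87 under the other settings that tested all of them. Signs were followed for genes of the naming rule and genes past the threshold in called families, so not for PSAE-1, LHCB4.1 or PSBW. Among the genes followed, signs turned when 1 array was left out only for genes that had not passed, and the cause was not tested. These were UF3GT (-0.163 to 0.773), DFR (-0.131 to 0.165), AT5G09570 (-0.027 to 0.234), WRKY47 (-0.124 to 0.196) and AT2G32730 (-0.336 to 0.110). List medians moved beyond their spread in 40 of 457 cases. Of the 10 splits of the arrays into groups of 3, the real one gave 3816 changes, 1977 of them at least 2-fold, and the highest other 0 for both by limma (at most 1524 at an unadjusted p under 0.05, against 5586), so 1 of 10 splits reached each count. Among the 4 splits that part all 3 pairs the highest other was also 0; the other 6 part 1 pair. With 10 splits no share can fall below 0.05. Signal near background limits the folds of dim genes.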

Other observations

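The families, the genes named from them and the tests on the arrays numbered 1 were chosen after the result was seen; the tests on ozone replicate 3 were set before, except for the comparison of its mixing estimate with the other arrays. Families were formed from the letters that open a current symbol, and the plastid-encoded loci formed a further group, which made 31 groups with at least 5 tested loci each. By camera with the preset correlation, 4 families were shifted with ozone, and with an estimated correlation 0 of the 31 were called. Of 6 tested plant U-box ubiquitin ligase genes (PUB) 4 rose, among them PUB24 (log2 fold change 2.01), PUB23 (1.56) and PUB43 (1.28), with a camera adjusted p of 0.00180, and adjusted p = 0.551 with an estimated correlation. Of 13 serine carboxypeptidase-like genes (SCPL) 7 fell and 0 rose (adjusted p = 0.0295, and adjusted p = 0.726 with an estimated correlation), with -1.41 for SCPL34, -1.15 for scpl26 and -0.90 for scpl42. Of 9 VPS genes, most of them parts of the machinery that sorts membrane proteins to the vacuole, 3 rose (adjusted p = 0.0295, and adjusted p = 0.726 with an estimated correlation): VPS60.1 (1.98), VPS20.1 (1.49) and VPS2.1 (1.46). The UDP-glycosyltransferase family (UGT) had 9 of 23 genes higher and 4 lower (adjusted p = 0.0368, and adjusted p = 0.551 with an estimated correlation). Among them UGT73B5, UGT73B4, UGT76B1 and UGT87A2 rose by log2 fold changes of 4.01, 3.66, 3.29 and 3.101, or 2.73, 2.80, 3.00 and 2.84 with 16 added to every signal. The control means of the first 2 were 9.90 and 17.3, so the order of the 4 is open.

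With 1 array left out the lower UGT genes numbered 1 to 5 and the higher ones 6 to 9, and 4 to 7 SCPL genes fell. With the replicate block 5 VPS genes rose and 1 fell, and the adjusted p of UGT was 0.0508. Median centring kept 2 families, PUB and SCPL, and leaving out both arrays numbered 1 kept 1, PUB. UGT was not called without ozone replicate 2, ozone replicate 3 or control replicate 1, nor with the filter at the 60th percentile, and VPS was not called without ozone replicate 1 or control replicate 2. Other groups were called under some settings only. The SEC symbols were called without the filter on dim probe sets and without ozone replicate 1. The plastid-encoded group was called without ozone replicate 1, and the ATG symbols without control replicate 1. With all arrays the plastid-encoded group had a median log2 fold change of -0.142 (camera adjusted p = 0.883). Without both arrays numbered 1 its camera adjusted p was 0.193. Plastid-encoded genes were brighter on both arrays numbered 1, so leaving out only ozone replicate 1 unbalances the groups.

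The arrays numbered 1 of both groups stood apart. On both, 47 of 64 plastid-encoded genes were brighter than the mean of the other arrays of their group, as were 2680 of 7186 other loci. The median log2 differences of the plastid-encoded genes were 0.69 in control and 0.78 in ozone, against -0.003 and -0.022 over the other loci. Unequal signal distributions cannot be the whole cause, since after quantile normalization the deviations of these 2 arrays still correlated at 0.737. The hybridization controls, which hold no plant RNA, were 1.71 times as bright on these arrays as on the other 4, as a separate hybridization batch could give. Each array is scaled to a trimmed mean of 100, so this ratio is relative to the other signals of an array and does not single out that cause. In 4 of 6 pairs of actin, GAPDH and ubiquitin probe sets the 3' to 5' ratio was higher on both arrays numbered 1 than on each other array, so shorter labelled product may contribute too. For 2 arrays picked at random chance gives 6.67% per pair. These arrays were picked because they stood apart, and the pairs share transcripts, so that share is no test here. No biological explanation was tested, and a difference between the plants of replicate 1 and the others stays open.

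Ozone replicate 3 had a smaller response, with a slope of 0.736 on the mean response of the other ozone arrays against 0.954 and 1.08 for replicates 1 and 2. After quantile normalization the slope was 0.771, with 0.831 among higher and 0.675 among lower genes, so unequal signal distributions are not the whole cause. Control RNA mixed into the sample would give the same share from higher and lower genes; the estimates were 0.321 from 494 higher and 0.187 from 93 lower probe sets, a difference of 0.134 (95% bootstrap interval over probe sets 0.085 to 0.178). This is past the bound of 0.1 set beforehand, but by the same method the difference was -0.241 for ozone replicate 1 and -0.034 (-0.081 to 0.037) for ozone replicate 2, so the method varies between arrays by more than the bound and such mixing stays open. A weaker response of these seedlings to ozone also stays open and was not tested.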
